A study of Mus musculus with 6 samples.

How the data were processed

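RNA was sequenced from 6 samples of colon tissue of C57BL/6J mice in the azoxymethane and dextran sulfate sodium (AOM/DSS) model, in which a single injection of the mutagen AOM is followed by rounds of the irritant DSS in the drinking water and tumours form in the colon. Per the labels' protocols, AOM was given at 10 mg/kg and DSS at 2% in 3 rounds, and part of the mice were also restrained in a ventilated 50 mL tube for 3 to 4 hours per day. The labels put 3 samples in the AOM/DSS group, called controls here, and 3 in the AOM/DSS group with restraint stress. Replicates were numbered within each group in accession order, so a number only names a sample. The labels call each sample colon tissue and give neither its place along the colon nor the hour or batch in which it was taken. They do not say in so many words that each sample is a separate mouse, and p-values measure the spread between these samples.

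The authors deposited a table of whole-number read counts per gene with 1 column per sample, per the file headers, and beside it FPKM values (fragments per kilobase, scaled to the depth of the sample), which the authors computed. The submitters' processing notes name fastp 0.19.3, HISAT2 2.1.0, featureCounts 1.6.2, StringTie 1.3.4d, DESeq2 1.22.1, edgeR 3.24.3 and the build GRCm39, without the role of each. The strand setting and the annotation are not given in the sources used here, so overlapping and antisense genes cannot be told apart, and counts of near-identical families such as the alpha-defensins are uncertain. Genes are named by the symbols in the table, and no coordinates are given because the reference used here is of another build. All tests used the counts. The deposited FPKM values served only as a check: among genes with at least 500 counts and an FPKM of at least 20, the count per unit of FPKM scaled between samples as the count totals did (0.937 to 1.14 times control replicate 1 by either measure).

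The table held 20170 genes, of which 249 had no count in any of the 6 samples. Total counts ran from 27160547 to 33017500 per sample. At these depths 3 counts, the limit that a count of 0 allows, correspond to 0.0909 to 0.110 counts per 1000000 counts (CPM). This limit covers counting error only, since reads without molecular identifiers are not independent molecules. The 10 genes with most counts took 3.91% to 5.26% of a sample. No 2 samples were alike within sampling noise: the chi-square per gene between pairs of samples was 40.7 or more, where sampling alone gives about 1.

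Genes were filtered with filterByExpr, which left 15890, scaled with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 with robust dispersions (R 4.3.3), with group as the term and Benjamini-Hochberg adjustment over the genes tested. The threshold was an adjusted p of 0.05. Log2 fold changes are stress minus control, and their standard error (SE) was taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled, and group values are means ± SD of 3 samples. A sample's score for a gene list is the mean log2 CPM of its members with a prior count of 2. Principal components were computed from log2 CPM of the 500 most variable genes. Scores were compared with a two-sided exact permutation test, whose smallest p for 3 samples against 3 is 0.1.

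A set of 43 gene lists covering cell types of the colon wall, epithelial lineages, immune cells, pathways and tissues that could be mixed in was fixed before the data were examined. Those with at least 3 tested members, 42 lists, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. A second set of 5 lists was chosen after seeing the data and adjusted separately. Members past the threshold were counted over all genes and adjusted over the list alone.

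The genes named were chosen by a rule fixed before the data were examined. Up to 10 genes per direction past the threshold were to be named; as none passed, the 5 of smallest p per direction were taken whose groups did not overlap and whose mean CPM was at least 1, leaving out predicted, receptor-segment and sex-linked genes. To these were added up to 4 members of smallest p in each list described, and Ctnnb1, Lgr5, Cd44, Prom1, Sox9, Axin2, Myc, Mki67, Fkbp5, Tsc22d3 and Per1 whatever their values. Some genes that this rule selects are not reported here. Notum, Arntl, Npas2, Nr1d1, Nr1d2, Tef, Cry1, Dbp, Lyz1, Hspa1a, Hspa1b, Tap1, Psmb8 and Sox2 were chosen after their values were seen.

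The test was checked on simulated counts drawn from the means, dispersions and library sizes of this comparison, with 200 genes changed. In edgeR it recovered 1.49% of the genes changed 1.5-fold, 28.4% of those changed 2-fold and 78.8% of those changed 4-fold, with 2 false calls among 15717 genes. DESeq2 recovered 10.4%, 55.2% and 87.9% (7 of 67, 37 of 67 and 58 of 66 genes), with 43 false calls among 15890 genes. The false share of its calls was thus larger than the threshold of 0.05 sets. Of 100 random lists of 15 unchanged genes, camera called 0 past an adjusted p of 0.05, in a simulation where genes varied independently of each other.

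The alternatives tried were RLE, upper-quartile and no scaling factors, no filter and a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, dispersions without the robust option, an added minimum log2 fold change of 1, and each sample left out in turn. A fit with the score of the Wnt and beta-catenin target list as a covariate was added after seeing the data. An alternative without immunoglobulin and T cell receptor segment genes was planned and not run, because no gene was matched to these classes by symbol.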

Results

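The colon transcriptome was profiled in 3 samples from mice given AOM/DSS alone (controls) and 3 from mice given AOM/DSS with daily restraint (stressed). Total counts were 28999355, 27160547 and 33017500 in control replicates 1, 2 and 3 and 32783104, 31314204 and 29690387 in stressed replicates 1, 2 and 3. Between 15457 and 16152 genes had at least 10 counts in a sample. The series title speaks of chronic stress, cancer stemness and colorectal tumorigenicity, and the comparison asks how expression in the colon differs between restrained and unrestrained AOM/DSS mice.

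In the stressed samples, genes of MHC class II antigen presentation, smooth muscle and enteric neurons stood lower as groups, and targets of Wnt and beta-catenin signalling and intestinal stem cell markers stood higher. These 5 lists passed camera at a preset correlation and none passed with an estimated correlation, where the adjusted p was 0.360 for MHC class II, 0.540 for smooth muscle, enteric neurons and stem cell markers, and 0.738 for Wnt targets. The Wnt target and stem cell lists share members. Cd74, the invariant chain of MHC class II, was measured at 1192 ± 269 CPM in controls and 399 ± 109 CPM in stressed samples (SD, n = 3 each). Acta2, the smooth muscle actin, was at 1109 ± 146 and 535 ± 95.3 CPM, and Axin2, a feedback inhibitor and target of Wnt signalling, at 88.0 ± 28.1 and 257 ± 120 CPM. For each of these genes the 3 values of one group lay outside the range of the other. No single gene passed the adjusted threshold in edgeR.

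By the edgeR quasi-likelihood test, 0 of 15890 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.191. At an unadjusted p under 0.05 there were 2644 genes, 1243 higher and 1401 lower, where 794 would be reached on average with no change. The balance depended on the scaling, with 1399 higher and 1203 lower by library size only and 1016 higher and 1582 lower by upper-quartile scaling. The other splits of the 6 samples into 3 and 3 gave 146 to 1713 genes, so 1 grouping can lie far from the average. DESeq2 called 810 genes, 352 higher and 458 lower, and limma-voom called 0, with 2591 at an unadjusted p under 0.05. Of the DESeq2 calls, 805 had an unadjusted p under 0.05 in edgeR. The groups did not overlap for 3775 genes, 23.8% of those tested, where chance gives 10% on average.

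Among genes whose groups did not overlap, the smallest p-values on the lower side belonged to Ogn, a small proteoglycan, Stmn2, a regulator of neuronal microtubules, Syne1, a nuclear envelope protein, Mustn1, a muscle protein, and Fgl2. Stmn2 had 22.9 ± 3.59 CPM in controls and 7.71 ± 0.606 in stressed samples, a log2 fold change of -1.57 ± 0.18 (SE). Ogn was at 67.3 ± 3.52 and 32.8 ± 3.82 CPM, with a log2 fold change of -1.04 ± 0.12. The log2 fold changes of Syne1, Mustn1 and Fgl2 were -0.997, -1.05 and -0.88. On the higher side stood Pim3, a serine/threonine kinase, Dlg5, a polarity scaffold, Fam60a, a chromatin regulator, and Fasn, the fatty acid synthase. Fasn was at 224 ± 10.6 CPM in controls and 366 ± 32.0 in stressed samples, a log2 fold change of 0.71 ± 0.11, and the others lay between 0.59 and 0.76. The edgeR adjusted p was 0.191 for each of these 9 genes, and DESeq2 called each of them.

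The samples were spread along 1 main axis. The first principal component held 61.0% of the variance of the 500 most variable genes and the second 19.8%. Control replicate 1 lay at -61.4 on the first component, control replicates 2 and 3 at -0.60 and -3.98, and stressed replicates 1, 2 and 3 at 0.69, 26.5 and 38.8. On this component stressed replicate 1 thus lay closer to control replicates 2 and 3 than to the other stressed samples. Over all tested genes its Spearman correlation was highest with stressed replicate 2, at 0.986. It was 0.981 and 0.983 with control replicates 2 and 3 and 0.972 with stressed replicate 3.

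**Figure D1:**
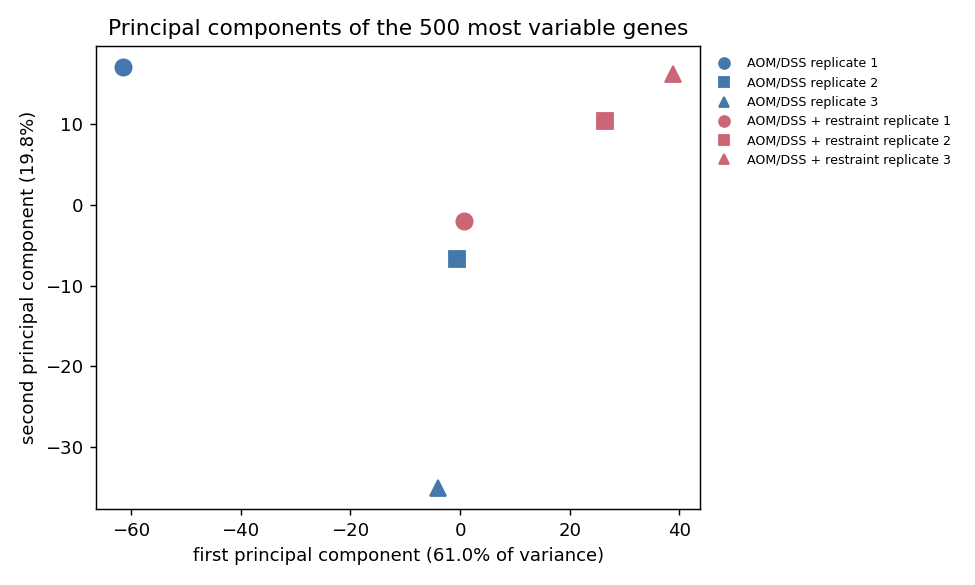
Positions of the 6 colon samples on the first and second principal components of the 500 most variable genes, with 1 point per sample. Control replicate 1 lies at -61.4 on the first component and stressed replicate 3 at 38.8, while stressed replicate 1 lies at 0.69, between the 3 controls and the other stressed samples.

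Of the 42 lists tested with camera, 13 passed an adjusted p of 0.05, 5 higher and 8 lower. By the same test 9 of the 10 splits of the 6 samples into 3 and 3, the real one among them, gave as many lists. The highest other split gave 24, so this count does not set the real grouping apart. With an estimated correlation 0 lists passed (smallest adjusted p = 0.360, and 3 lists at an unadjusted p under 0.05), and fry called 0 (smallest adjusted p = 0.115, and 5 lists at an unadjusted p under 0.05). No member of any list passed over all genes tested in edgeR.

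**Figure D2:**
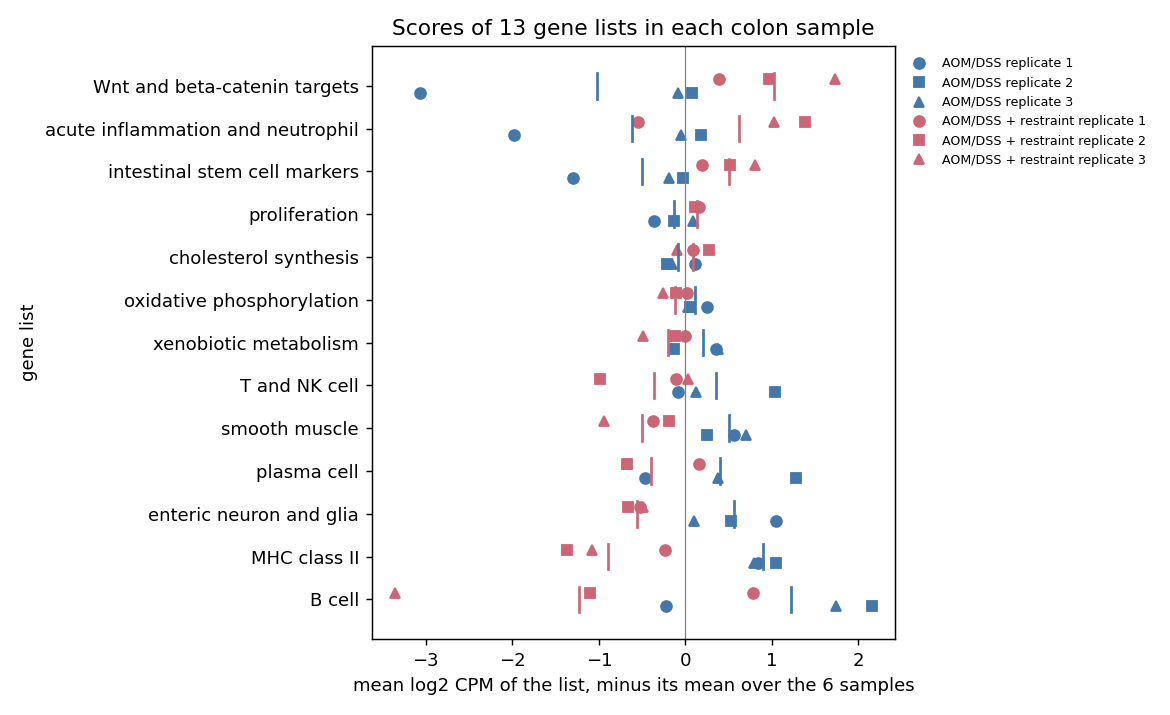
Score of each of the 13 lists past the threshold in each sample, as the mean log2 CPM of its members minus the mean over the 6 samples, with vertical bars at the group means. The groups do not overlap for MHC class II, smooth muscle, enteric neuron and glia, Wnt targets, stem cell markers, proliferation and oxidative phosphorylation, and control replicate 1 lies lowest for Wnt targets.

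The MHC class II list stood lower in stressed samples, with all 9 tested members lower and a median log2 fold change of -1.58 (camera adjusted p = 6.7e-18). The adjusted p was 0.360 with an estimated correlation. Adjusted over the list alone 7 members passed, against 0 over all genes. H2-Aa, a class II alpha chain, was at 639 ± 175 CPM in controls and 171 ± 67.3 in stressed samples, and H2-DMa and H2-DMb1, which load peptides onto class II, had log2 fold changes of -1.57 ± 0.22 and -1.39 ± 0.20. Markers of B cells, which carry MHC class II, had a median of -1.87 and 14 of 14 members lower (camera adjusted p = 1.6e-06, and adjusted p = 0.850 with an estimated correlation). Between the groups the scores of these markers overlapped (exact permutation p = 0.2). Their score was 5.64 and 5.23 in control replicates 2 and 3, 3.27 in control replicate 1, and 4.27, 2.38 and 0.14 in stressed replicates 1, 2 and 3. Pax5, a transcription factor of B cells, was at 8.19 ± 6.54 CPM in controls and 1.44 ± 1.45 in stressed samples, and 0 members of the B cell list passed adjusted over the list alone. Without stressed replicate 1 the B cell median was -3.56.

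The other lymphoid lists stood lower by smaller margins. The T and NK cell list had a median of -0.90 with 15 of 19 members lower (camera adjusted p = 8.7e-04, and adjusted p = 0.850 with an estimated correlation). Klrd1 and Nkg7, genes of cytotoxic lymphocytes, had log2 fold changes of -1.60 ± 0.38 and -1.35 ± 0.43, Ccl5 of -1.63 ± 0.54 and Cd8a of -1.17 ± 0.46. The plasma cell list had a median of -1.23 with 10 of 11 members lower (camera adjusted p = 0.0306, and adjusted p = 0.850 with an estimated correlation), with Irf4 at 11.5 ± 6.25 and 4.88 ± 3.26 CPM. In either list 0 members passed adjusted over the list alone. Without control replicate 2 neither list passed (medians -0.21 and -0.22), and the plasma cell list also missed the threshold without stressed replicate 3 (median -1.013).

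The smooth muscle list stood lower, with 14 of 14 members lower and a median of -1.04 (camera adjusted p = 1.7e-17, and adjusted p = 0.540 with an estimated correlation). All 14 passed adjusted over the list alone, against 0 over all genes. Besides Acta2, Tagln was at 1267 ± 193 CPM in controls and 599 ± 109 in stressed samples, and Myl9 and Mylk, of the contractile apparatus, had log2 fold changes of -1.10 ± 0.21 and -1.05 ± 0.21. The enteric neuron and glia list stood lower with 17 of 18 members and a median of -1.33 (camera adjusted p = 4.4e-13, and adjusted p = 0.540 with an estimated correlation). Of its members 13 passed adjusted over the list alone. Prph, a neuronal intermediate filament, was at 26.1 ± 9.73 CPM in controls and 9.002 ± 1.62 in stressed samples, and Gap43 and Tubb3 had log2 fold changes of -1.33 ± 0.24 and -1.24 ± 0.24. The fibroblast and endothelial lists did not pass, with medians of 0.16 and 0.19 (camera adjusted p = 0.309 and 0.212). Without control replicate 2 both passed as higher (medians 0.51 and 0.51), and without control replicate 1 the medians were -0.0041 and -0.0517.

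The Wnt and beta-catenin target list stood higher with all 22 members and a median of 1.68 (camera adjusted p = 4.4e-13, and adjusted p = 0.738 with an estimated correlation). Adjusted over the list alone 4 members passed, which were Ccnd1, Ephb2, Sox4 and Axin2. Sox4 was at 27.01 ± 14.1 CPM in controls and 103 ± 17.3 in stressed samples, and Ccnd1, cyclin D1, at 110 ± 10.5 and 174 ± 6.83. The list's score was 2.19 in control replicate 1, 5.34 and 5.17 in control replicates 2 and 3, and 5.64, 6.22 and 6.98 in stressed replicates 1, 2 and 3. Notum, a secreted Wnt inhibitor, was at 0.885 CPM in control replicate 1, against 109 and 65.2 in control replicates 2 and 3 and 104, 156 and 465 in the stressed samples.

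The intestinal stem cell markers stood higher with 15 of 15 members and a median of 0.82 (camera adjusted p = 1.5e-08, and adjusted p = 0.540 with an estimated correlation), and 4 members passed adjusted over the list alone. Lgr5, Ascl2, Tnfrsf19, Ephb2 and Ephb3 also belong to the Wnt target list, so these lists are not independent. The score was again lowest in control replicate 1, at 4.42, against 5.69 and 5.53 in control replicates 2 and 3. It was 5.91, 6.24 and 6.52 in stressed replicates 1, 2 and 3. Ephb2, an Eph receptor of the crypt base, was at 58.3 ± 5.49 CPM in controls and 83.1 ± 1.10 in stressed samples, and Cdca7, Rnf43 and Ephb3 had log2 fold changes of 0.52 ± 0.13, 1.216 ± 0.33 and 0.51 ± 0.15. Lgr5, the receptor that marks crypt stem cells, was at 0.811, 50.5 and 21.5 CPM in control replicates 1, 2 and 3 and at 51.4, 85.6 and 119 CPM in the stressed samples (edgeR adjusted p = 0.425). The separate list of cancer stemness markers did not pass, with 6 members higher, 6 lower, a median of 0.01 and a mean of -0.33, and the direction of the test was lower (camera adjusted p = 0.640). Sox2 was at 7.27 CPM in control replicate 3, the sample with squamous keratins, and at 0.0613 to 0.769 CPM in the other 5, and without it the mean of the other 11 members was -0.11. Its members Dclk1 and Aldh1a1 had log2 fold changes of -0.93 ± 0.22 and -0.96 ± 0.30, Cd24a had 0.54 ± 0.16, and 1 member passed adjusted over the list alone. Among the markers fixed by name, log2 fold changes were 0.03 ± 0.29 for Prom1, 0.45 ± 0.28 for Cd44, 0.21 ± 0.12 for Sox9, 0.22 ± 0.17 for Myc and 0.32 ± 0.13 for Ctnnb1. Their edgeR adjusted p was 0.294 or more, where the smallest of any gene was 0.191. For Ctnnb1 the groups did not overlap (1014 to 1191 CPM in controls and 1241 to 1535 in stressed samples). Leaving out a sample gave 0.20 to 0.72 for Cd44 and 0.07 to 0.34 for Myc.

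The proliferation list stood slightly higher, with 19 of 23 members and a median of 0.20 (camera adjusted p = 1.3e-04, and adjusted p = 0.850 with an estimated correlation). The 3 members that passed adjusted over the list alone were Mcm2, Mcm3 and Mcm7, subunits of the replicative helicase, with log2 fold changes of 0.66 ± 0.14, 0.64 ± 0.14 and 0.65 ± 0.16. Mki67, a general marker of cycling cells, was at 290 ± 60.1 and 285 ± 29.4 CPM. Without control replicate 3 the list's median was 0.37. The cholesterol synthesis list stood higher with 14 of 20 members and a median of 0.18 (camera adjusted p = 0.0255, and adjusted p = 0.850 with an estimated correlation), with 0 members adjusted over the list alone; it missed the threshold without control replicate 2 or 3 (medians 0.12 and 0.15) or stressed replicate 1 or 2 (medians 0.23 and 0.12). Insig1, a regulator of sterol synthesis, had a log2 fold change of 0.64 ± 0.15.

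The acute inflammation and neutrophil list stood higher with 22 of 24 members and a median of 0.95 (camera adjusted p = 1.7e-04, and adjusted p = 0.850 with an estimated correlation), and 0 members passed adjusted over the list alone. Its members of smallest p included the matrix proteases Mmp13, at 10.9 ± 8.86 CPM in controls and 87.8 ± 98.0 in stressed samples, and Mmp10, at 14.7 ± 15.6 and 84.3 ± 65.9. The list's score was 1.74 in stressed replicate 1, within the range of the controls, and its median was 0.48 without control replicate 1 and 0.38 without stressed replicate 2. The xenobiotic metabolism list stood lower with 20 of 23 members and a median of -0.53, and the oxidative phosphorylation list with 23 of 25 and a median of -0.25 (camera adjusted p = 7.0e-04 for each, and adjusted p = 0.777 and 0.850 with an estimated correlation). Ces1f and Gstm3, enzymes of detoxification, had log2 fold changes of -1.47 ± 0.31 and -1.12 ± 0.34, and Cox6c, a subunit of cytochrome c oxidase, of -0.43 ± 0.14. In the first 1 member and in the second 0 passed adjusted over the list alone, and without control replicate 1 the medians were -0.31 and -0.17.

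**Figure D3:**
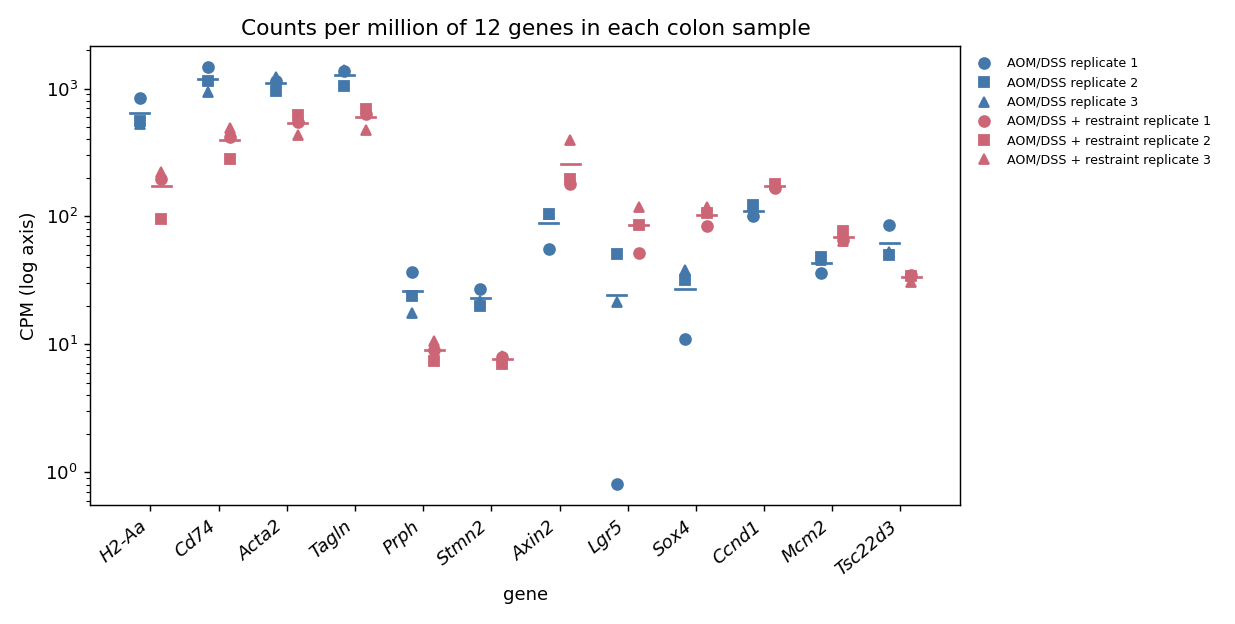
CPM of 12 genes in each of the 6 samples on a log axis, with horizontal bars at the group means. Cd74 and Acta2 are lower and Axin2 and Sox4 higher in the stressed samples without overlap, and Lgr5 runs from 0.811 CPM in control replicate 1 to 119 CPM in stressed replicate 3.

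The list of glucocorticoid-responsive genes did not pass, with 7 members higher, 13 lower, a median of -0.15 and a mean of 0.0065, and the direction of the test was lower (camera adjusted p = 0.459). Leaving out each sample in turn gave medians from -0.21 to 0.0343. Adjusted over the list alone 4 members passed, 1 higher and 3 lower, against 0 over all genes. Tsc22d3, the glucocorticoid-induced leucine zipper, was at 62.4 ± 19.9 CPM in controls and 33.3 ± 2.08 in stressed samples. Nfkbia and Cebpd had log2 fold changes of -0.54 ± 0.13 and -0.71 ± 0.19, and Ddit4 of 0.97 ± 0.27. Fkbp5 was at 55.6 ± 29.7 and 42.5 ± 18.7 CPM and Per1 at 28.04 ± 1.07 and 25.4 ± 1.58. The goblet cell and absorptive colonocyte lists did not pass (medians 0.10 and -0.70, camera adjusted p = 0.494 and 0.173). The goblet cell list passed as higher without control replicate 1 or stressed replicate 3 (median 0.32 in each), and the colonocyte list as lower without control replicate 2 or stressed replicate 1 (medians -0.84 and -0.82). Car4 and Slc26a3, of mature colonocytes, were at 690 ± 521 and 552 ± 486 CPM in controls and 247 ± 109 and 198 ± 89.6 in stressed samples. Control replicate 1 held 1272 and 1103 CPM of them, and without it their log2 fold changes were -0.69 and -0.48, against -1.48 for each with all samples.

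Keratins of squamous epithelium were high in 1 library. Krt5 was at 890 CPM in control replicate 3 and at most 0.67 CPM in the other 5 samples, and all 11 tested members of the squamous list were highest there. The list did not pass (median -3.23, camera adjusted p = 0.309), and without control replicate 3 its median was 1.40, in the opposite direction, past the threshold at a camera adjusted p of 2.97e-04.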

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

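The fit with the Wnt target score as a covariate was chosen after seeing the data; the other alternatives were planned. The count of genes past the threshold was 0 in edgeR under every scaling, filter and left-out sample tried, with the covariate and in limma-voom, and 810 in DESeq2. In the simulated counts DESeq2 recovered 55.2% of 2-fold changes, against 28.4% in edgeR, but made 43 false calls, against 2. The 43 stood beside 7, 37 and 58 recovered genes changed 1.5-fold, 2-fold and 4-fold, a larger false share than the threshold of 0.05 sets. The share of false calls among the 810 is not known, and the cause of the gap was not tested further. Every named gene that DESeq2 called had the same direction in edgeR. Genes at an unadjusted p under 0.05 numbered 2644, and 1429 and 1602 without stressed replicate 2 or 3, in fits with fewer samples, and 1669 with the covariate. Of the 13 lists past the threshold, 10 passed in the same direction in all 11 other camera fits at the preset correlation. The exceptions were T and NK cell, plasma cell and cholesterol synthesis, which lost it in 1, 3 and 4 of these fits (the plasma cell list with a median of -1.10 under the stricter filter as well as without 2 of the samples), and no other. With an estimated correlation and in fry 0 lists passed, at unchanged medians: MHC class II -1.58, smooth muscle -1.04, enteric neuron and glia -1.33, B cell -1.87, T and NK cell -0.90, plasma cell -1.23, xenobiotic metabolism -0.53, oxidative phosphorylation -0.25, Wnt targets 1.68, stem cell markers 0.82, acute inflammation 0.95, proliferation 0.20 and cholesterol synthesis 0.18. These tests allow for genes of a list varying together between samples.

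Some lists not past the threshold passed it under another scaling or filter: skeletal muscle with library size only (-1.02) and with no filter (-1.97), and interferon response with no filter (-0.33). For others the direction of the test turned without passing, at medians below 0 with either direction (glycolysis -0.0533, small intestine enterocyte -0.17 and adipocyte -0.11 at the main settings, where the test pointed higher). These were glycolysis with upper-quartile scaling (-0.0711), the stricter filter (-0.0590) and fry (-0.0533), small intestine enterocyte with library size only (-0.14) and in fry (-0.17), and adipocyte with the stricter filter (-0.20). The cause was not tested. The first principal component held 50.4% of the variance over all tested genes, against 61.0% over 500.

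Leaving out each sample in turn gave medians of -1.15 to -0.21 for T and NK cell, -1.82 to -0.22 for plasma cell and 0.12 to 0.26 for cholesterol synthesis. Among lists not past the threshold, the medians ran from -0.19 to 0.32 for goblet cell, -0.84 to -0.14 for absorptive colonocyte, -0.59 to -0.11 for tuft cell, -0.77 to -0.19 for enteroendocrine cell, -0.0887 to 0.0654 for tight junction, -0.36 to 0.66 for monocyte and macrophage, -0.62 to -0.13 for interferon response, -0.72 to -0.23 for immune checkpoint and -0.16 to 1.01 for mast cell. They ran from -0.0041 to 0.51 for fibroblast, -0.0517 to 0.51 for endothelial cell, -0.31 to 0.14 for adipocyte, -3.98 to 1.40 for squamous epithelium, -1.31 to -0.31 for skeletal muscle, -1.70 to -0.12 for pancreatic acinar, -0.29 to 0.13 for small intestine enterocyte and -0.14 to 0.87 for distal Hox. They ran from -0.32 to 0.0083 for fatty acid oxidation, -0.15 to 0.0147 for hypoxia, -0.10 to 0.0516 for glycolysis, -0.16 to 0.0342 for unfolded protein response, -0.19 to 0.30 for EMT and -0.17 to 0.0499 for sex-linked genes. For glucocorticoid-responsive genes the range was -0.21 to 0.0343, and for cancer stemness markers -0.18 to 0.0927. Of these, goblet cell, tuft cell, squamous epithelium, skeletal muscle and immune checkpoint passed without control replicate 1. Without control replicate 2 absorptive colonocyte, monocyte and macrophage, fatty acid oxidation, fibroblast, endothelial cell, pancreatic acinar, squamous epithelium and skeletal muscle passed, and without control replicate 3 interferon response, mast cell and, in the opposite direction, squamous epithelium. Absorptive colonocyte and enteroendocrine cell passed without stressed replicate 1, interferon response and pancreatic acinar without stressed replicate 2, and goblet cell and skeletal muscle without stressed replicate 3. These fits have fewer samples.

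Log2 fold changes of named genes that changed sign did so from values that did not pass: Mki67 with library size only (0.0150), and on leaving out a sample Mki67 (-0.15 to 0.15), Prom1 (-0.27 to 0.26), Fkbp5 (-0.80 to 0.13), Krt5 (-10.07 to 1.17), Krt6a (-7.22 to 1.61) and Krtdap (-5.38 to 1.48), the keratin genes without control replicate 3, which held most of their counts. With the Wnt target score as a covariate the values were -0.31 for Lgr5, -0.0420 for Cd44, -0.0861 for Myc, -0.81 for Notum, 0.52 for Fkbp5, 0.0173 for Krt20 and 0.24 for Slc26a3. Of these, Lgr5, Cd44, Myc and Notum are members of the list that makes the score. No paired analysis was possible because the sample labels share no replicate numbers between the groups. Depth was 27160547 to 33017500 counts per sample, and in simulated data of this size edgeR recovered 28.4% of 2-fold changes.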

Other observations

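The 5 lists of this part, and every test in it except those over the splits of the samples and of the circadian clock genes, were chosen after results had been seen. The clock list itself was added later, but its test was set down when Per1 was its 1 member already looked at. Adjusted p-values of these lists are over the 5 lists. The covariate tests were first set at 2 SE, that of control replicate 1 at the list's threshold and that of the Hox score at a fixed size of rho, and by these rules every explanation left open by them would have been argued against; that the 95% interval must also exclude the bound was added after this outcome had been seen. For a loss of non-epithelial tissue, the rule set down asked, besides the medians, that each list's interval exclude the smooth muscle difference of -1.004. This held, at -0.60 to 0.92 for fibroblast and -0.70 to 1.17 for endothelial cell. Another version also required the smooth muscle score to move apart from each of these lists by an interval excluding 0, which left the explanation open. That 1 such interval is enough was decided after both had been seen.

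Genes of Paneth cells and alpha-defensins stood higher in stressed samples, with 15 of 15 members and a median log2 fold change of 3.14 (camera adjusted p = 3.1e-08, and adjusted p = 0.222 with an estimated correlation). Lyz1, the Paneth cell lysozyme, was at 8.22, 342 and 131 CPM in control replicates 1, 2 and 3 and at 283, 1453 and 1150.5 CPM in stressed replicates 1, 2 and 3, so stressed replicate 1 lay within the range of the controls. Adjusted over the list alone 0 members passed. Heat shock genes stood lower with 11 of 12 members and a median of -0.81 (camera adjusted p = 2.6e-06, and adjusted p = 0.222 with an estimated correlation), and 5 passed adjusted over the list alone. Hspa1a and Hspa1b, the inducible chaperones, were at 50.5 ± 49.2 and 135 ± 107 CPM in controls and 5.16 ± 1.59 and 19.0 ± 5.40 in stressed samples. The MHC class I and antigen processing list stood lower with 15 of 15 members and a median of -0.58 (camera adjusted p = 2.9e-09, and adjusted p = 0.137 with an estimated correlation), and 8 members passed adjusted over the list alone, among them Tap1 and Psmb8. In fry, with adjustment over the 5 lists, the adjusted p was 0.0363 for this list and for interferon gamma responsive genes, both lower, which share 5 members, and 0.158 or more for the Paneth cell, heat shock and clock lists.

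The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. In edgeR all 10 splits gave 0 genes past the threshold, so the real 0 and the highest other 0 were equal. In DESeq2 the real split gave 810 genes and the highest other 290, and 1 split, the real one, gave as many. At an unadjusted p under 0.05 the real split gave 2644 genes and the highest other 1713, again with 1 split, the real one, giving as many. For gene lists the real split gave 13 and the highest other 24, and 9 of the 10 splits gave as many as the real one. A count of lists past camera at the preset correlation thus does not set the real grouping apart from others.

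A pattern to follow up is the lower MHC class II, smooth muscle and enteric neuron lists. Fewer B cells as the whole source of the MHC class II difference are argued against only weakly. With the B cell score as a covariate the group difference of the MHC class II score was -1.41 ± 0.42 (SE), against -1.79 without it. The 95% interval ran from -2.74 to -0.07. This leans on control replicate 1, with an MHC class II score of 6.75 and a B cell score of 3.27, below the 4.27 of stressed replicate 1. Without that sample the B cell scores of the groups do not overlap, and the fit was not repeated without it. Less non-epithelial tissue of every kind as the whole source of the smooth muscle difference is argued against by the fibroblast list alone. The smooth muscle score moved apart from that list by -1.16 (95% interval from -2.24 to -0.09). The interval against the endothelial list, from -2.67 to 0.19, included 0. That 1 interval is enough was decided after both had been seen, so this is weak evidence. It concerns only a loss of every kind of such tissue. Less muscle wall in the stressed samples as the source of the smooth muscle difference was not tested and stays open. Lower interferon gamma signalling stays open. Interferon gamma responsive genes outside MHC class II stood lower in 21 of 22 members (camera adjusted p = 8.9e-09, and adjusted p = 0.137 with an estimated correlation). That list was chosen after results had been seen, in the test that gave as many lists in 9 of the 10 splits. Its members that passed adjusted over the list alone, Psmb10, Psmb8, Psmb9 and Tap1, also belong to the MHC class I list. The interferon response list fixed beforehand, which shares 7 of its members, did not pass (median -0.33, 16 of 22 members lower, camera adjusted p = 0.0696, and adjusted p = 0.850 with an estimated correlation). A larger share of tumour in the stressed tissue cannot be told apart from stress: with the Wnt target score as a covariate the differences were -1.69 ± 0.55, -0.83 ± 0.38 and -0.70 ± 0.28 for MHC class II, smooth muscle and neurons, against -1.79, -1.004 and -1.11 without it, each beyond 2 SE, but the 95% intervals on 3 degrees of freedom included 0. Less muscle wall as the source of the lower neuron list stays open. With the smooth muscle score as a covariate the difference was -1.39 ± 0.68, against -1.11 without it, with a 95% interval from -3.55 to 0.78. The smooth muscle score itself separated the groups, at 7.80 to 8.25 in controls and 6.62 to 7.36 in stressed samples. The fit can therefore hardly tell it from the group and does not decide. Restraint itself is untested.

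The higher Wnt and beta-catenin target list rests in part on control replicate 1. Without it the median was 1.27 and the list stayed past the threshold, but the difference of the scores was 1.03 ± 0.50 (SE), with a 95% interval from -0.57 to 2.64, so the low values of that sample as the whole source cannot be excluded. Position along the colon also stays open: the Wnt target and distal Hox scores had a Spearman rho of -0.26 (exact permutation p = 0.658) and a Pearson r of 0.19 (exact permutation p = 0.815; 0.14 without the 2 samples farthest in Hox score), and 6 samples allow a rho from -0.88 to 0.70. Whether that sample held less tumour, or stress gave more, was not measured.

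The squamous keratins of control replicate 3 may come from tissue of the anal margin in that sample. Of the 10 tested skeletal muscle genes, a list not chosen for this pattern, 8 were also highest in that sample, where chance gives 1 in 6 for each (binomial p = 1.9e-05, with genes that are not independent). Both lists were fixed before the data were examined as tissues that could be mixed in. No biological explanation was tested, since the pattern is in 1 sample.

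A difference in the hour at which tissue was taken may set the groups apart. The expectation written beforehand was that clock genes would pass adjusted over their list alone. The activators (Arntl, Clock, Npas2) and the repressed arm (Dbp, Nr1d1, Nr1d2, Ciart, Per3) were to move apart. Of 18 members 5 passed, Arntl (-1.20 ± 0.27) and Cry1 (-1.19 ± 0.23) lower and Nr1d1 (0.99 ± 0.29), Nr1d2 (1.05 ± 0.29) and Tef (0.93 ± 0.27) higher, and 0 over all genes in edgeR. The 3 activators, with Npas2 at -0.53 ± 0.17, were all lower and the 5 genes of the other arm, with Dbp at 1.08 ± 0.43, all higher. A shift of the clock by restraint predicts the same, and the sources used here give no hour, so this hypothesis and an effect of stress remain open, also for other genes whose level follows the time of day.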
